A study of Mus musculus with 18 samples.

How the data were processed

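RNA was measured in 18 libraries of E14Tg2a mouse embryonic stem cells, 3 independent replicates for each of 6 groups, made by crossing genotype (wild type or Daxx-null) with culture (serum with LIF, 2i with vitamin C, or retinoic acid). Per the labels' protocols, RNA was treated with DNase, and polyadenylated RNA was enriched with an oligo-dT step as well as depleted of ribosomal RNA, whereas the series design speaks of depletion of ribosomal RNA from total RNA. Strand was not given in the sources used here, so overlapping and antisense genes cannot be told apart. The labels do not say how the replicates were separated in time or culture, so p-values measure the spread between these samples.

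The authors deposited gene values as FPKM per library for 24505 RefSeq entries, each with its accession, symbol and mm9 position. Per the submitters' processing notes, Bowtie2 2.2.6, HOMER 4.8 and limma (version not given) were used with the mm9 build. The sum of each library's values times length exceeds 1 M units (1 M is 1000000), so these FPKM were not scaled to a total of 1 M. No label states the scale. A total of 10 M was inferred, of which 58.16 to 60.96% then lay in gene exons. On that scale a value is about 10 times a conventional FPKM. The authors also deposited FPKM of 906 repeat subfamilies, divided by the number of copies and by mean length. They were scaled to a separate read set that, on the same inferred scale, lies mostly in repeats. A repeat value is therefore a share of repeat reads and does not follow the total amount of repeat RNA. A further table holds log2 values, which the authors made by quantile normalization of all libraries and addition of a pseudocount of 1. This was checked against the FPKM, with a largest difference of 0.0024 among genes above the median. That table served as an alternative.

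Depth was recovered from the FPKM, because values of low genes are whole multiples (within a tolerance of 0.1) of the worth of 1 counting unit in each library. It ranged from 84.2 to 141.7 M units for genes. On the same scale the repeat read set ranged from 8.04 to 18.96 M units. That is 11.8 ± 0.658% of the gene set in Daxx-null and 11.3 ± 0.814% in wild-type serum and 16.3 ± 2.78% and 14.7 ± 1.80% in 2i. In retinoic acid it is 7.18 ± 0.223% and 7.54 ± 0.125% (SD, n = 3). The differences were 0.527 (exact two-sided permutation p = 0.5), 1.64 (p = 0.4) and -0.363 (p = 0.1) percentage points, and 0.1 is the smallest exact permutation p that 3 against 3 allows. Precision of each value is set by the spread of 3 replicates, and a low gene rests on few units.

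Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a trend of variance on mean, for 18002 genes at an FPKM of at least 1 in at least 3 libraries. Repeats were tested on log2(FPKM + 0.526), the pseudocount being the 5th percentile of values above 0, for 834 subfamilies above 0 in at least 9 libraries. All 18 libraries entered one fit with 6 group means and a shared estimate of spread. The contrasts were Daxx-null minus wild type in each culture, the difference of that effect between 2i and serum and between retinoic acid and serum, and 2i and retinoic acid minus serum in wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all genes of a contrast. A fold change is on the log2(value + pseudocount) scale, which understates the change of low genes. The deposited log2 values were tested in the same way.

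Gene lists were fixed before the data were examined, along with the groups, tests, filters, pseudocounts, repeat lists and the first set of alternatives. There were 22 gene lists with 589 members, of which 580 matched by symbol, and lists needed at least 5 tested genes or 3 tested repeat subfamilies. They covered Daxx partners and silencing factors, DNA methylation, pluripotency, primed epiblast, neural, retinoic acid response and Hox, endoderm, mesoderm and trophoblast genes. Others were two-cell-like state, germline, imprinted, p53, interferon, fibroblast, glial, neural crest, blood and endothelium, glycolysis, cholesterol synthesis, G2/M and centromere genes. Repeat lists were IAP, MMERVK10C with RLTR10, ETn with MusD, MERVL with MT2, MaLR, leukaemia virus with VL30, young L1, satellites, and SINE B1 and B2. A telomere-like list had 0 tested subfamilies and gave no result. Lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation. Members were also adjusted over the list alone.

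Named genes followed a rule. Per culture it took the 8 largest and 8 smallest log2 fold changes among genes with an adjusted p under 0.05, all 3 libraries of one genotype beyond all 3 of the other, and a mean FPKM of at least 2 in the higher genotype. Predicted, clone, Riken, microRNA and small nucleolar names were left out. It also took 3 called members per list that camera called or that had at least 3 called genes. For each difference between cultures it took 5 genes in each direction, whether or not replicates overlapped, and for each wild-type contrast 4 members of each of 6 lists. Repeats were 6 subfamilies in each direction and 7 fixed ones. Those most telling for the account are given in the text. The rule was passed by 4462 genes in serum, 6699 in 2i and 348 in retinoic acid. For 3 replicates against 3, chance gives groups that do not overlap in 10% of genes. Y-linked and X-linked neighbours, the genes of Daxx-null 2i replicate 2, and the genes listed to show wild-type 2i replicate 3 were chosen after their values were seen.

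The procedure was tested on simulated data. Of genes changed 2-fold, 70% were recovered in serum, 75% in 2i and 69% in retinoic acid, and 99% of those changed 4-fold in each. There were 10, 11 and 12 false calls among 17426, 17426 and 17427 unchanged genes. Of repeats changed 2-fold 93.3%, 93.3% and 90% were recovered. Of those changed 4-fold it was 93.3%, 93.3% and 100%, with 4, 5 and 2 false calls among 772. The simulation used 1 dispersion for all genes (0.0299) and 1 for all repeats (0.0112), the same in all libraries, so a library that stands apart was not simulated. Only 100 genes were changed at each fold, and no shift of chromosomes or of the median of all genes was put in. Recovery and false calls therefore describe an easier setting than the data.

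Alternatives were other pseudocounts and filters, quantile normalization, median-ratio scaling, the authors' table and fits of only the groups compared. Others were a replicate block, each library left out, an estimated correlation, and repeats without simple repeats. Those added after the data were seen are the removal of each chromosome's median shift, leaving out Daxx-null 2i replicate 2 from every fit, and leaving it out with wild-type 2i replicate 3. So are leaving out the 3 wild-type libraries numbered 3, repeats on the all-read scale, and the leukaemia virus list without RLTR40 to RLTR47. Between wild-type 2i and serum, same-numbered libraries deviated together (r = 0.146, 0.171 and 0.326 across genes), all above 0.1. These are paired by that check alone, although replicates 1 and 2 were interchangeable (0.129 and 0.172). Deviations cancel out within a group, so a replicate 3 that stands apart makes replicates 1 and 2 correlate in any order. The check therefore links only replicate 3. Between wild-type retinoic acid and serum these correlations were all under 0.1 (0.0198, 0.0434 and 0.0874), so the numbers were not taken to pair them. Replicate 3 nevertheless correlated best with its own number (0.0874 against at most -0.0325 with the others). Its chromosome shifts were also shared between these cultures (r = 0.948 across 20 chromosomes), so its number may link them. The GENCODE vM21 annotation, of another build, served only for the GC content of transcripts by symbol. Its positions were not used. Figures were drawn with matplotlib 3.10.9. Read-level data were not analysed here. Some single-gene results are not reported here.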

Results

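RNA was sequenced from 18 libraries of male mouse embryonic stem cells of the E14Tg2a line, wild type or null for Daxx, the histone chaperone that deposits the histone variant H3.3 with Atrx. Each genotype was grown in 3 cultures: serum with leukaemia inhibitory factor (LIF, 1000 units/mL), 2i with vitamin C (100 µg/mL), which holds cells in the ground state, and retinoic acid (24 h without LIF, then 4 days with 10 µM retinoic acid), which starts differentiation. Every group had n = 3 libraries. Depth was worked out from the steps between low values on an inferred scale of 10 M (1 M is 1000000). The wild-type depths in M counting units were 84.2, 91.66 and 92.8 in serum, 105, 91.83 and 98.33 in 2i, and 116.4, 141.7 and 120.7 in retinoic acid. The Daxx-null depths were 109.9, 126.4 and 115.9 in serum, 113.5, 103.6 and 95.98 in 2i, and 115.2, 135.2 and 138.8 in retinoic acid. Expression is given in FPKM as the authors scaled it, by inference about 10 times a conventional FPKM, and ± is the SD over n = 3 libraries. Adjusted p-values are from limma, and fold changes are log2 differences of Daxx-null minus wild type.

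Daxx itself (NM_007829, mm9 chromosome 17, 34046390 to 34052535, plus strand) was lower in each of the 9 Daxx-null libraries than in any wild-type library. In serum its FPKM was 68.7, 72.2 and 73.7 in Daxx-null replicates 1 to 3 against 307, 319 and 353 in wild type. In 2i it was 54.4, 56.0 and 57.6 against 434, 423 and 402, and in retinoic acid 62.7, 61.7 and 60.8 against 238, 242 and 265. The log2 fold change was -2.18 (SE 0.0716, adjusted p = 2.4e-11) in serum, -2.89 (adjusted p = 4.7e-13) in 2i and -2.0 (adjusted p = 3.7e-11) in retinoic acid. Which part of the gene was deleted is not given in the sources used here, so the remaining signal does not measure intact transcript. How many Daxx-null clones were used is not given either. Loss of Daxx therefore cannot be told apart from other differences between the lines. Below, the Daxx effect means the difference of Daxx-null minus wild type.

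Male cells carry Eif2s3y (Y, 347055 to 365037), Uty (Y, 433587 to 582202) and Ddx3y (Y, 597158 to 623056), and their summed FPKM separated the Daxx-null cultures. It was 220.6 ± 55.2 in wild-type serum, where replicate 3 was low (258.4, 246.1 and 157.3 in replicates 1 to 3). It was 159.6 ± 5.01 in wild-type retinoic acid and 335.9 ± 19.7 in wild-type 2i. Daxx-null libraries held 2.48 ± 0.265 in serum and 1.78 ± 0.722 in retinoic acid, which is 1.13% and 1.11% of wild type. They held 205 ± 31.7 in 2i, which is 61% of wild type. The Daxx-null cells of 2i thus differed from those of the other cultures in Y-linked RNA as well as in medium, and differences between cultures in the Daxx effect cover both.

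**Figure D1:**
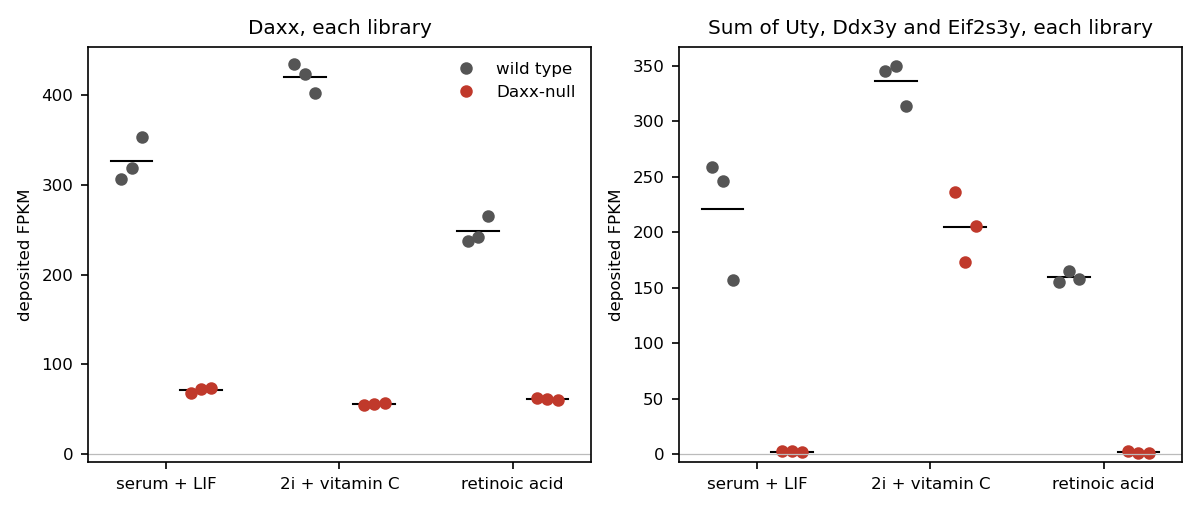
Daxx and the sum of Eif2s3y, Uty and Ddx3y, in FPKM, in each of the 18 libraries (points) by genotype and culture. Daxx-null libraries lie between 54.4 and 73.7 FPKM for Daxx, under every wild-type library, and the Y-linked sum is 2.48 in Daxx-null serum and 205 in Daxx-null 2i.

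The first comparison asked how Daxx-null cells differed from wild-type cells in serum, the usual culture of these cells. Among pluripotency regulators, Klf5 (chromosome 14, 99697910 to 99712628), which sustains self-renewal, reached 1852 ± 54.3 against 694 ± 13.9 FPKM (log2 1.42, SE 0.182, adjusted p = 5.6e-05). Nr0b1 reached 1293 ± 364 against 476 ± 32.5 (1.41). Bmp4, a signal for mesoderm and germ cells, rose from 123 ± 28.1 to 394 ± 19 (1.69, adjusted p = 7.7e-06). The endoderm regulator Gata4 (chromosome 14, 63817751 to 63864108) went from 18.5 ± 2.39 to 1.95 ± 0.183 FPKM (-2.95, adjusted p = 4.7e-04). Srgn, which encodes a secreted proteoglycan, went from 40.8 ± 7.08 to 2.73 ± 0.294 (-3.67, adjusted p = 2.5e-05). The imprinted gene H19 (NR_130973, chromosome 7, 149761435 to 149764051) was among the deepest falls, at 3.09 ± 1.51 against 217 ± 63.8 FPKM (-5.97, SE 0.917, adjusted p = 2.4e-04).

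In total 1672 genes were higher and 3406 lower in Daxx-null serum cells of 18002 tested, of which 360 and 1323 changed at least 2-fold. The glutamate receptor subunit Grin2c (chromosome 11, 115110483 to 115128557) rose most, from 4.69 ± 1.01 to 98.8 ± 3.15 FPKM (4.28, SE 0.338, adjusted p = 6.0e-07). Slc23a1, a vitamin C transporter, reached 103 ± 15.5 against 9.62 ± 1.43 (3.35, adjusted p = 1.5e-07). Samd5 rose by 4.03 on the log2 scale, the transcription factor Creb5 by 3.44, the receptor gene Gpr83 by 3.43 and the X-linked histone chaperone gene Nap1l2 by 3.29. Apart from H19, the deepest falls included those of the Y-linked Eif2s3y (-6.32), Uty (-5.39) and Ddx3y (-5.22) and of X-linked genes of germ cells and placenta, namely Fmr1nb (-5.93), Xlr3a (-5.82), Pnma5 (-4.69) and Xlr3b (-4.66). The Xlr, Tuba3, Rhox, Zscan4 and Pramel genes have near-identical copies, so the division of reads among members is uncertain. Leaving out wild-type serum replicate 3 took the higher count to 1079.

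Of the fixed gene lists in serum, the naive pluripotency list had 7 rises and 2 falls of 28 genes (8 and 2 adjusted over the list alone; adjusted p = 9.2e-04, 0.754 with an estimated correlation). Primed epiblast genes rose in 3 cases and fell in 0 of 18, with Grhl2 at 144 ± 1.75 against 36.5 ± 8.74 FPKM (1.99) and Foxd3 at 1.36. Its list p was 0.022 (0.754 with an estimated correlation; 0.0766 with the shift of each chromosome removed). Partners of Daxx and other silencing factors had 11 rises and 1 fall of 30, among them Atf7ip (305 ± 5.95 against 181 ± 32.1 FPKM, 0.77) and Asf1a (0.74), with adjusted p = 1.8e-04 (0.385 with an estimated correlation). Adjusted over the list alone these were 12 and 3. The endoderm list fell, with 2 rises and 13 falls of 28 (2 and 13 adjusted over the list alone) and Col4a2 at -2.82 (list adjusted p = 9.0e-04, 0.754 with an estimated correlation).

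Glycolysis genes fell in 13 and rose in 0 of 21 (15 falls adjusted over the list alone; adjusted p = 8.7e-06, 0.754 with an estimated correlation), including Bnip3 (147 ± 14.0 against 579 ± 24.7 FPKM, -1.98), Eno2 (11.9 ± 4.18 against 62.9 ± 16.5, -2.38) and Aldoc (-1.70). Fibroblast genes fell in 10 of 21 and rose in 0, with Col1a1 at -2.59 (10 falls adjusted over the list alone; adjusted p = 0.0338, 0.783 with an estimated correlation). Of the genes of the two-cell-like state, 4 rose and 2 fell of 28, the falls being Pramel6 (-3.40) and Pramel7 (-2.80). Quantile normalization gave 9 and 2 for this list, and 0 and 5 for fibroblast genes. The two-cell-like list was called higher with adjusted p = 0.0455 (4 and 2 adjusted over the list alone; 0.801 with an estimated correlation, 0.094 under median-ratio scaling and 0.14 with chromosome shifts removed).

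Lists not called as a body in serum still held strong single changes. Germline genes whose promoters carry DNA methylation fell in 12 cases and rose in 2 of 42 (15 and 2 adjusted over the list alone; adjusted p = 0.179), with Tuba3a at 37.3 ± 11.4 against 319 ± 47.2 FPKM (-3.11). Imprinted genes fell in 12 and rose in 2 of 45 (adjusted p = 0.216): Nnat fell from 146 ± 42.3 to 10.5 ± 2.29 FPKM (-3.71), and the growth inhibitor Grb10 from 272 ± 50.3 to 21.2 ± 5.04 (-3.66). Cdkn1c rose (1.77). Interferon genes fell in 10 and rose in 2 of 40, including Oas1b at -1.81 (adjusted p = 0.182). Targets of p53 fell in 8 and rose in 4 of 30 (adjusted p = 0.433), with the cell cycle inhibitor Cdkn1a at 234 ± 9.81 against 609 ± 67.2 FPKM (-1.37) and Pmaip1 at 1.03. Mesoderm genes rose in 4 and fell in 6 of 25 (adjusted p = 0.954), Evx1 (2.60) and Tal1 (1.71) among the rises. Quantile normalization turned this to 4 and 2. Retinoic acid response and Hox genes fell in 8 and rose in 0 of 33 (7 falls adjusted over the list alone; adjusted p = 0.212). Cholesterol synthesis genes fell in 8 and rose in 2 of 19, with Insig1 at -0.93 and Dhcr7 at -0.86 (adjusted p = 0.179). Under quantile normalization rises and falls were 1 and 2 for the retinoic acid response and Hox list (2 and 7 under median-ratio scaling), 2 and 7 for germline, 3 and 8 for imprinted, and 2 and 5 for cholesterol synthesis genes (2 and 4 under median-ratio scaling).

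Neural genes rose in 3 and fell in 1 of 40 in serum, with Pax6, the eye and forebrain regulator, at 32.7 ± 1.47 against 11.4 ± 1.79 FPKM (1.49; list adjusted p = 0.422). Rises and falls were 2 and 4 of 20 trophoblast genes (0.738), 2 and 1 of 13 DNA methylation genes (0.406), 2 and 0 of 15 neural crest genes (0.272), the value in brackets being the list's adjusted p. They were 0 and 3 of 11 glial genes (0.179), 0 and 4 of 12 blood and endothelial genes (0.116; 6 falls adjusted over the list alone), 0 and 4 of 20 G2/M genes (0.383), and 2 and 1 of 16 centromere genes (0.448). The centromere rises, Hjurp (0.57) and Nuf2 (0.38), both lie on chromosome 1. For the DNA methylation, neural, trophoblast and centromere lists the test pointed up while median and mean were below 0. Quantile normalization turned the median of the trophoblast list (-0.151 to 0.0528), and, like median-ratio scaling, those of the DNA methylation list (-0.0346 to 0.0492) and the centromere list (-0.0565 to 0.0174).

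The median of all genes lay at -0.121 in serum, so the split of calls depended on scaling. Of called genes 32.9% were higher as deposited, 51% after quantile normalization, 45.9% after median-ratio scaling, 50.8% in the authors' normalised table and 52.8% with chromosome shifts removed. Quantile normalization moved the median to 0.0104. Changes much larger than this shift, such as those of Klf5, Gata4, Grin2c and H19, do not turn on it.

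The same comparison of Daxx-null and wild-type cells was made in 2i, in ground-state cells, whose DNA is weakly methylated. Interferon-responsive genes rose as a body: 32 rose and 0 fell of 40 (33 and 0 adjusted over the list alone; adjusted p = 1.2e-06, 0.546 with an estimated correlation). The chemokine gene Cxcl10 (chromosome 5, 92775665 to 92777915) reached 43.5 ± 19 against 1.69 ± 1.53 FPKM (4.65, SE 0.587, adjusted p = 2.0e-05). The immunoproteasome gene Psmb8 reached 93.4 ± 16.0 against 7.78 ± 6.56 (4.24, adjusted p = 3.2e-04) and the guanylate-binding protein gene Gbp2 174 ± 51.3 against 13.9 ± 11.1 (4.27, adjusted p = 4.6e-04). Genes of cell division fell: 0 rose and 17 fell of 20 G2/M genes (adjusted p = 1.5e-09, 0.00223 with an estimated correlation). Kif11, the spindle motor, stood at 151 ± 15.7 against 305 ± 24.0 FPKM (-1.01, adjusted p = 3.2e-06) and the checkpoint gene Bub1b at 261 ± 26.9 against 443 ± 25.9 (-0.77, adjusted p = 3.3e-06). The X-linked homeobox gene Rhox9 rose from 61.7 ± 41.9 to 836 ± 223 (4.09), and Dppa3, which protects the maternal genome from demethylation, from 35.5 ± 19.7 to 349 ± 89.0 (3.46, adjusted p = 4.6e-06).

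In 2i 5671 genes were higher and 2760 lower in Daxx-null cells, 3103 and 689 of them at least 2-fold. Besides Cxcl10, the largest rises included Lnp1 (83.7 ± 38.9 against 2.43 ± 1.82 FPKM, 5.02, adjusted p = 1.6e-06), the iron exporter gene Slc40a1 (267 ± 61.3 against 12.4 ± 9.40, 4.87) and the hormone gene Cck (58.4 ± 2.50 against 2.22 ± 1.41, 4.62). Gbp2b rose by 4.43 and Rassf4 by 4.28. Among the deepest falls were the homeobox genes Hoxa11 (-3.93) and Nkx1-2 (-3.88), Apol6 (2.07 ± 0.364 against 37.9 ± 12.5 FPKM, -3.85) and Etv4, a target of FGF signalling (34.4 ± 15.6 against 456 ± 19.4 FPKM, -3.81, adjusted p = 7.4e-07). The tetraspanin gene Cd37 fell from 316 ± 28.9 to 25.9 ± 9.19 (-3.65, adjusted p = 9.0e-07). Wild-type 2i replicate 3 stood apart and low for many of the genes that rose. Its FPKM was 0.335 for Psmb8 against 10.3 and 12.7 in its sisters, 1.08 for Gbp2 against 20.7 and 19.9, and 14.7 for Rhox9 against 75.2 and 95.2. Without it the higher count was 4615. With only the groups compared 2724 genes were higher and 1205 lower.

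Groups that rose in 2i included two-cell-like genes with 21 rises and 0 falls of 28 (21 and 0 adjusted over the list alone; Sp110 3.48; list adjusted p = 5.8e-04, 0.546 with an estimated correlation). Targets of p53 had 21 and 2 of 30 (22 and 2 adjusted over the list alone; Plk2 2.03, Perp 1.97; adjusted p = 0.00152, 0.546 with an estimated correlation). Trophoblast genes had 13 rises and 2 falls of 20, with Rhox6 (740 ± 160 against 69.3 ± 45.9 FPKM, 3.76) and Krt18 (413 ± 65.0 against 40.2 ± 27.3, 3.70). That list had adjusted p = 0.0031 (14 and 2 adjusted over the list alone; 0.546 with an estimated correlation). Endoderm genes had 17 and 1 of 28, with Dab2 (121 ± 12.6 against 19 ± 13.3 FPKM, 3.05), Cited1 (2.46) and Lamb1 (2.31). The endoderm list had adjusted p = 0.00893 (17 and 1 adjusted over the list alone; 0.546 with an estimated correlation, and 0.123 without both Daxx-null replicate 2 and wild-type replicate 3).

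The G2/M genes (17 falls adjusted over the list alone) fell in 2i at adjusted p = 1.5e-09 (0.00223 with an estimated correlation). Centromere genes had 1 rise and 9 falls of 16, including Incenp (-0.85) and Cenpb (-0.84), at adjusted p = 2.4e-04 (1 and 9 adjusted over the list alone; 0.0403 with an estimated correlation). Pluripotency genes had 4 and 13 of 28, with Lin28a (55.3 ± 3.88 against 226 ± 89.4 FPKM, -1.94) and Gdf3 (264 ± 54.5 against 743 ± 85.3, -1.51), at adjusted p = 0.00148 (4 and 13 adjusted over the list alone; 0.546 with an estimated correlation). Cholesterol synthesis genes had 1 and 10 of 19, with Mvk at 103 ± 11.8 against 282 ± 74.5 FPKM (-1.43), at adjusted p = 3.3e-04 (1 and 11 adjusted over the list alone; 0.546 with an estimated correlation). Silencing partners had 5 and 9 of 30, with Cbx3 (-0.91), Smarcad1 (-0.74) and Cbx5 (-0.73), at adjusted p = 0.00893 (0.516 with an estimated correlation; 5 and 9 adjusted over the list alone). Glycolysis genes had 1 and 8 of 21, with Pfkp at -1.20, at adjusted p = 0.00573 (0.546 with an estimated correlation, and 0.125 without both Daxx-null replicate 2 and wild-type replicate 3). DNA methylation genes had 2 and 7 of 13 at adjusted p = 0.0185 (0.136 with an estimated correlation), Dnmt3a being a rise (0.80).

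Germline genes rose in 19 and fell in 3 of 42 in 2i (21 and 3 adjusted over the list alone; adjusted p = 0.051, 0.00784 without Daxx-null replicate 2), with the meiotic gene Sycp2 at 2.75 and Slc25a31 at 2.02. Imprinted genes rose in 18 and fell in 7 of 45 (adjusted p = 0.737): Peg10 reached 1970 ± 960 against 225 ± 36.7 FPKM (3.02) and Cdkn1c 276 ± 141 against 34.8 ± 23.5 (3.24). Grb10 fell (-1.64). H19 was not called (0.51, adjusted p = 0.671), and its wild-type FPKM was 527, 429 and 14.6 in replicates 1 to 3 against 165, 298 and 197 in Daxx-null cells, so that wild-type replicate 3 sets the sign. Under quantile normalization the imprinted list had 13 rises and 11 falls, and its median went from 0.333 to 0.0416. Blood and endothelial genes rose in 7 and fell in 1 of 12, with Runx1 at 2.50 (list adjusted p = 0.126, and 0.0437 without Daxx-null replicate 2). Fibroblast genes had 7 rises and 1 fall of 21 (adjusted p = 0.144), and glial genes 3 and 0 of 11, with Mbp at 2.69 (adjusted p = 0.345). Primed epiblast genes rose in 3 and fell in 6 of 18, with Tcf15 at -2.47, Dusp6 at -1.87 and Lef1 at 2.10 (list adjusted p = 0.0788, and 0.0437 without Daxx-null replicate 2).

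Daxx-null 2i replicate 2 carried neural RNA that its sisters lacked. Its FPKM was 177.4 for Dcx against a sister mean of 0.591, 192 for Map2 against 7.66, and 87.36 for Gfap against 0.372. Neural genes rose in 7 and fell in 2 of 40 in 2i (list adjusted p = 0.388), and without that library the list turned downward at adjusted p = 0.0371. Retinoic acid response and Hox genes rose in 7 and fell in 3 of 33 (adjusted p = 0.726, and 0.0157 downward without the same library), with Cdx1 at 142 ± 50.7 against 990 ± 450 FPKM (-2.78). Their test pointed down with a median of 0.185, which quantile normalization turned to -0.0643, with 6 rises and 5 falls. Mesoderm genes rose in 6 and fell in 4 of 25 (adjusted p = 0.514, Hand1 2.78), with a test pointing down and a median of 0.1 that quantile normalization turned to -0.655. Neural crest genes rose in 5 and fell in 0 of 15 (adjusted p = 0.299), with Krt5 at 1.81 and a median of 0.443 that quantile normalization turned to -0.0415.

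The median of all genes was 0.199 in 2i (-0.0334 after quantile normalization, 0.114 after median-ratio scaling). The share of called genes that were higher was 67.3% as deposited, 47% after quantile normalization, 59.2% after median-ratio scaling, 46.9% in the authors' table and 50.4% with chromosome shifts removed. Under quantile normalization interferon genes still had 30 rises and 0 falls, G2/M genes 0 and 15, two-cell-like genes 13 and 0, p53 targets 21 and 2, trophoblast genes 13 and 2 and endoderm genes 12 and 2. Pluripotency genes had 4 and 8, blood and endothelial genes 5 and 2, neural genes 5 and 3 and neural crest genes 3 and 1.

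**Figure D2:**
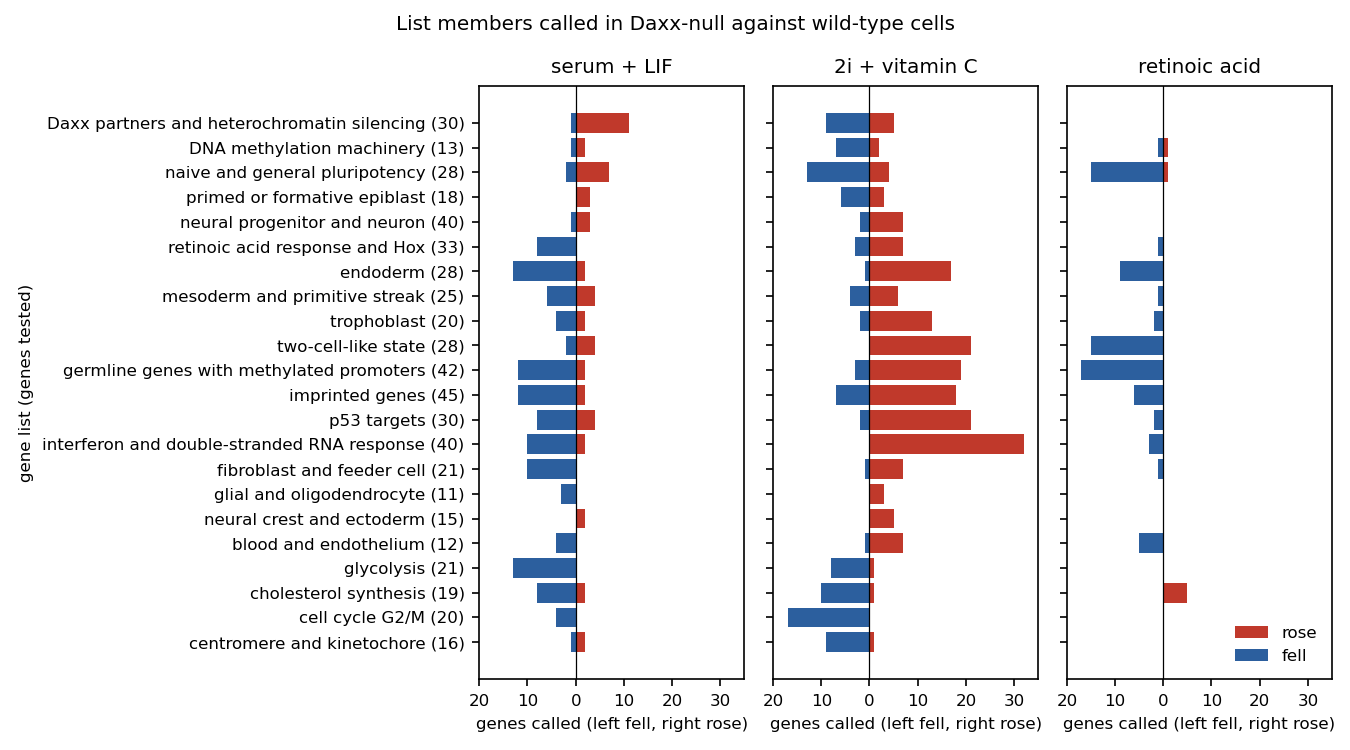
Number of genes that rose (right) or fell (left) in Daxx-null cells at adjusted p under 0.05, for each of the 22 gene lists (bars) and each culture (panels). Interferon genes stand at 32 rises and 0 falls in 2i and at 2 and 10 in serum, and counts of the mesoderm list in serum and 2i turn to mostly the other direction under quantile normalization.

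The third comparison asked how Daxx-null cells differed from wild-type cells after retinoic acid. Among genes of the undifferentiated state, Dppa2 (chromosome 16, 48310387 to 48319626), an activator of early embryonic genes, stood at 2.68 ± 0.834 against 11.4 ± 2.26 FPKM (-1.93, SE 0.252, adjusted p = 3.0e-04). The two-cell-stage gene Zscan4d stood at 2.91 ± 0.233 against 24.5 ± 5.19 (-2.86, adjusted p = 0.00442), and the germ cell gene Rpl10l at 0.804 ± 0.454 against 17.2 ± 5.12 (-3.78, adjusted p = 6.6e-08). The tubulin gene Tuba3a was at 1.21 ± 0.676 against 17.2 ± 1.77 (-3.46, adjusted p = 5.3e-07). Of imprinted genes, H19 was at 32.3 ± 15.2 against 6810 ± 1227 FPKM (-7.82, adjusted p = 9.9e-05). Grb10 (chromosome 11, 11830502 to 11927974) was at 4.97 ± 0.852 against 680 ± 77.7 (-6.97, SE 0.209, adjusted p = 9.5e-12) and Nnat (chromosome 2, 157385814 to 157388261) at 11.5 ± 4.13 against 1017 ± 32.6 (-6.46, adjusted p = 5.1e-07). The neural list had 0 rises and 0 falls of 40 in limma (adjusted p = 0.0142 upward, 0.672 with an estimated correlation and 0.0956 with chromosome shifts removed). Pax6 stood at 219 ± 40.1 against 196 ± 20 FPKM. Over all genes 2257 had an unadjusted p under 0.05.

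In retinoic acid 40 genes were higher and 408 lower in Daxx-null cells, 5 and 313 of them at least 2-fold. The chemokine gene Cxcl13 rose from 6.53 ± 1.95 to 18.6 ± 2.11 FPKM (1.47, adjusted p = 0.00199), Nmnat2 on chromosome 1 by 1.48, and the histone gene H2afx from 1846 ± 190 to 3189 ± 282 (0.79, adjusted p = 0.00452). The Y-linked and X-linked genes named in serum were again low, with Eif2s3y at -6.93, Fmr1nb at -5.92, Uty at -5.46 and Xlr3a at -5.44, and Xlr4a listed at 0 in the 3 Daxx-null libraries against 11.9 ± 2.38 FPKM. Without wild-type replicate 3 the higher count was 16 and the lower count 224, and Nmnat2 was no longer called. Without Daxx-null replicate 2 these counts were 17 and 225. Without Daxx-null replicate 1 the higher count was 16, and without wild-type replicates 1 and 2 in turn it was 20 and 23. Leaving out Daxx-null 2i replicate 2, which this comparison does not use, gave 85 higher genes, and leaving out wild-type 2i replicate 3 as well gave 225 higher and 872 lower. With only the groups compared the lower count was 268.

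Germline genes fell in 17 and rose in 0 of 42 in retinoic acid (22 falls adjusted over the list alone; adjusted p = 6.6e-20, 0.0738 with an estimated correlation). Two-cell-like genes fell in 15 and rose in 0 of 28 (21 and 1 adjusted over the list alone; adjusted p = 6.6e-20, 0.0738 with an estimated correlation). Pluripotency genes fell in 15 and rose in 1 of 28 (18 and 2 adjusted over the list alone; adjusted p = 6.3e-11, 0.0889 with an estimated correlation). Pou5f1 was at 3.29 ± 0.455 against wild-type values of 13.8, 18.6 and 73.9 FPKM. Both are far below wild-type serum (7704, 7975 and 8380 FPKM), so the difference lies within a small remainder of this RNA. Endoderm genes fell in 9 and rose in 0 of 28 (17 falls adjusted over the list alone; adjusted p = 1.7e-12, 0.0889 with an estimated correlation). Srgn stood at -3.00 and Cubn at -3.06, whose wild-type FPKM was 25.4, 23.8 and 106. Blood and endothelial genes fell in 5 and rose in 0 of 12, Cd34 at 1.34 ± 0.292 against 8.38 ± 0.900 FPKM and Tie1 and Cdh5 with it (6 falls adjusted over the list alone; adjusted p = 1.2e-07, 0.0738 with an estimated correlation).

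Cholesterol synthesis genes rose in 5 and fell in 0 of 19 in retinoic acid (8 and 0 adjusted over the list alone; adjusted p = 1.5e-15, 0.0738 with an estimated correlation). Sqle stood at 607 ± 1.88 against 419 ± 37.9 FPKM (0.54) and Idi1 at 157 ± 13.2 against 95.4 ± 11.4 (0.72). Both single calls were lost without wild-type replicate 3, at adjusted p = 0.0602 and 0.062. Lists called lower were p53 targets with 2 falls of 30 (3 adjusted over the list alone; adjusted p = 1.9e-05, 0.392 with an estimated correlation) and interferon genes with 3 of 40, including Irf1 at -0.75 (adjusted p = 0.00111, 0.55 with an estimated correlation). Imprinted genes had 6 falls of 45 (7 adjusted over the list alone; adjusted p = 0.0201, 0.57 with an estimated correlation). Besides the neural list given above, lists called higher with 0 single calls were G2/M (adjusted p = 9.8e-04, 0.0738 with an estimated correlation), glycolysis (0.00447 and 0.528), centromere (0.0103 and 0.0889) and silencing partners (0.0142 and 0.289).

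The remaining lists were not called in retinoic acid. Their adjusted p was 0.549 for DNA methylation genes (1 rise and 1 fall, Dnmt3l falling by 3.24), 0.35 for primed epiblast, 0.932 for retinoic acid response and Hox, 0.109 for mesoderm, 0.35 for trophoblast (2 falls), 0.314 for fibroblast, 0.173 for glial and 0.782 for neural crest genes. Median and mean differed in sign for the retinoic acid response and Hox list (0.0284 and -0.0757) and for the neural crest list (0.0493 and -0.0149). Quantile normalization turned the medians of the retinoic acid response and Hox, trophoblast, glial and primed epiblast lists, none of them called. Under it 9 pluripotency, 10 germline and 5 endoderm genes fell and 3 cholesterol synthesis genes rose. Of called genes 8.93% were higher as deposited, 18.5% after quantile normalization, 10.8% after median-ratio scaling and 18.1% in the authors' table. Over all 3 cultures and both differences between cultures, the list calls that held with an estimated correlation were G2/M in 2i, centromere in 2i and the G2/M difference between 2i and serum (adjusted p = 0.0239).

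Among repeats in serum, the young L1 elements L1Md_T, at 6.78 ± 0.354 against 2.45 ± 0.322 FPKM (1.30, adjusted p = 4.3e-04), and L1Md_A, at 9.45 ± 0.997 against 4.02 ± 0.667 (1.14, adjusted p = 0.0022), rose. The leukaemia virus element RLTR4_MM-int rose too, at 59.6 ± 0.514 against 25.1 ± 1.26 (1.23, adjusted p = 4.7e-07). In 2i the endogenous retroviruses MMERVK10C-int (27.5 ± 2.61 against 6.29 ± 0.719, 2.04, adjusted p = 1.2e-07) and IAPEz-int (113 ± 6.52 against 42.4 ± 8.81, 1.42, adjusted p = 1.4e-05) rose. MMETn-int fell (124 ± 3.06 against 397 ± 41.6, -1.67, adjusted p = 3.6e-08). Among subfamilies called in retinoic acid, the largest fall was of ORR1A3-int (4.14 ± 0.285 against 6.87 ± 0.227, -0.67, adjusted p = 7.0e-04). A repeat value is a share of a separate set of mostly repeat reads, and how reads with several positions were assigned is not given in the sources used here, so division among related subfamilies is uncertain.

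Of 834 repeat subfamilies tested, 30 were higher and 63 lower in serum, 153 and 48 in 2i, and 1 and 6 in retinoic acid. At least 2-fold changes numbered 7 and 6, 18 and 9, and 0 and 0. The share of calls that were higher went from 32.3% to 54.9% in serum under quantile normalization (60.3% with the genes' median-ratio factor, 43.1% on the all-read scale). It went from 76.1% to 32% in 2i (59.5% and 89.4%) and from 14.3% to 0% in retinoic acid (16.7% and 0%). Leaving out any 1 library moved the serum counts to between 18 and 27 higher and between 29 and 40 lower, and in 2i the lower count without wild-type replicate 3 was 26. In retinoic acid the higher count was 0 and the lower count 2 without Daxx-null replicate 1, without Daxx-null replicate 2 or without wild-type replicate 1, and 0 and 3 without Daxx-null replicate 3. With only the groups compared the 2i counts were 28 and 8. Without Daxx-null 2i replicate 2 the lower count was 98 in serum, and the counts in retinoic acid were 2 and 14. Without wild-type 2i replicate 3 as well they were 56 and 161 in serum and 11 and 71 in retinoic acid, and 100 were higher in 2i. With a replicate block the counts were 17 higher and 33 lower in serum and 0 and 0 in retinoic acid, where ORR1A3-int then had adjusted p = 0.0621, and LTR40b and RLTR4_MM-int 0.111.

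In serum LTR40b (1.28) and RLTR4_Mm (1.30) also rose, MMERVK10C-int rose by 0.61 and IAPEz-int by 0.73 (14.2 ± 0.751 against 8.36 ± 1.01 FPKM, adjusted p = 0.00661). ETnERV3-int fell (1.64 ± 0.313 against 5.96 ± 0.263, -1.60). In 2i IAPLTR1_Mm (1.64), the long terminal repeat of IAP elements, and RLTR10C (1.73) rose while ETnERV-int (-1.48) and RLTRETN_Mm (-1.35) fell. The major satellite GSAT_MM was not called in serum (0.44, adjusted p = 0.177) or in retinoic acid (-0.06, adjusted p = 0.909). It was called in 2i (0.59, adjusted p = 0.0499) but not without Daxx-null replicate 2 (adjusted p = 0.18). MERVL-int, active in two-cell-like cells, was called in 2i at 0.87 (adjusted p = 0.0306), but not without Daxx-null replicate 2 (0.114) or wild-type replicate 3 (0.131). It was also called in serum at 0.93 (adjusted p = 0.0428), but not without Daxx-null replicate 2 (0.105) or 3 (0.12), without wild-type replicate 1 (0.0552) or 3 (0.169), or with a replicate block (0.0749). In retinoic acid LTR40b rose (0.96) and RLTR4_MM-int fell (-0.54, adjusted p = 0.00569). There IAPEz-int was not called (0.57, adjusted p = 0.0725) except without wild-type replicate 3 (0.73, adjusted p = 0.0433).

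Of the fixed repeat lists, young L1 was called in serum with 4 rises and 0 falls of 12 (adjusted p = 0.0133, 0.163 with an estimated correlation and 0.0701 with a replicate block). In 2i the IAP list had 11 rises and 0 falls of 16 and the MMERVK10C and RLTR10 list 7 and 0 of 9 (both adjusted p = 7.3e-05, 0.13 with an estimated correlation). ETn and MusD fell in 4 of 5 (adjusted p = 1.3e-10, 0.0075 with an estimated correlation). In retinoic acid MaLR elements had 1 fall of 44 (adjusted p = 3.3e-04, 0.779 with an estimated correlation). The leukaemia virus and VL30 list had 1 fall of 21 (adjusted p = 2.8e-04, 0.00569 with an estimated correlation). The repeat calls that held with an estimated correlation were this last one, ETn and MusD in 2i, and the difference of ETn and MusD between 2i and serum (0.0235). The leukaemia virus list takes in RLTR40 to RLTR47, which only share its first characters, and without them its retinoic acid p was 3.3e-04.

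Repeat lists that were not called had adjusted p in serum of 0.502 (IAP, 3 rises and 2 falls), 0.51 (MMERVK10C and RLTR10), 0.385 (ETn and MusD) and 0.394 (MERVL and MT2, 2 and 0 of 7). There they were also 0.385 (MaLR, 1 and 6), 0.828 (leukaemia virus and VL30, 3 and 4), 0.51 (satellites) and 0.51 (SINE B1 and B2). In 2i they were 0.338 (MERVL and MT2, 2 and 0), 0.338 (MaLR, 10 and 1), 0.338 (leukaemia virus and VL30, 5 and 4), 0.28 (young L1, 4 and 1), 0.0932 (satellites) and 0.338 (SINE). In retinoic acid they were 0.632 (IAP), 0.196 (MMERVK10C and RLTR10), 0.632 (ETn and MusD), 0.632 (MERVL and MT2), 0.724 (young L1), 0.909 (satellites) and 0.909 (SINE). Quantile normalization took MaLR in 2i from 10 rises and 1 fall to 1 and 13 and young L1 in 2i from 4 and 1 to 0 and 1. It took SINE in 2i from 2 and 0 to 2 and 4 and leukaemia virus elements in serum from 3 and 4 to 3 and 2. The genes' median-ratio factor took ETn and MusD in serum from 0 and 1 to 3 and 1 and MaLR in serum from 1 and 6 to 2 and 1. Quantile normalization also turned the list median in serum of IAP (-0.0196 to 0.0663) and MERVL and MT2, in 2i of the leukaemia virus list, and in retinoic acid of young L1. Median and mean differed in sign in serum for the IAP list (-0.0196 and 0.00297), the ETn list (0.199 and -0.158), and the MERVL list (-0.0766 and 0.164), and in 2i for the SINE list (-0.0365 and 0.0399). The test pointed up while median and mean were below 0 for the MMERVK10C and leukaemia virus lists in serum and for satellites in retinoic acid. It pointed down while both were above 0 for the leukaemia virus list in 2i.

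**Figure D3:**
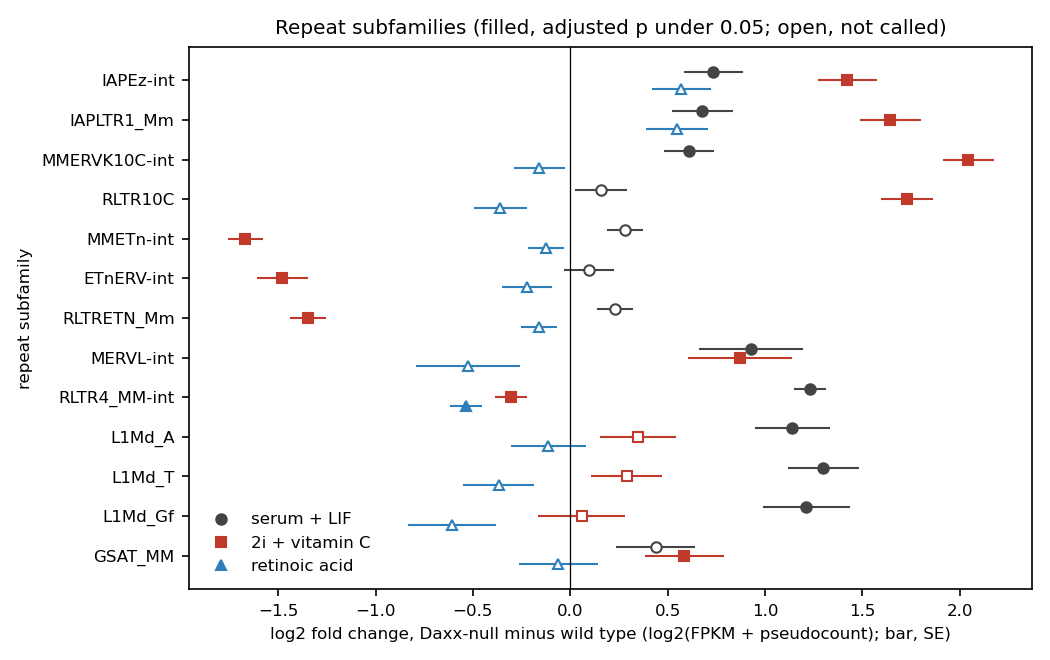
Log2 fold change of Daxx-null minus wild type (points, with SE bars) of 13 repeat subfamilies in each culture, filled where limma's adjusted p was under 0.05. MMERVK10C-int reaches 2.04 in 2i and MMETn-int -1.67, while L1Md_T stands at 1.30 in serum.

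The Daxx effect was also compared between cultures, and for 2i this covers the difference in Y-linked RNA as well as that in medium. The effect in 2i minus that in serum, in log2, was 6.31 for Cxcl10 (SE 0.83, adjusted p = 3.9e-05), which rose in 2i (4.65) and fell in serum (-1.66). It was 6.48 for H19 (adjusted p = 0.00104, and 4.82 without wild-type 2i replicate 3) and 5.84 for Fmr1nb (adjusted p = 1.2e-06), which fell in serum and were not called in 2i. The response of Nkx6-3 was -4.29 (adjusted p = 5.6e-07) and that of Cd37 -4.17 (adjusted p = 6.3e-06). Between retinoic acid and serum the differences were -4.44 for Grin2c (adjusted p = 8.6e-05), -3.84 for Slc23a1 (adjusted p = 1.4e-05), -3.75 for Zscan4d (adjusted p = 0.0048) and 3.12 for the germ cell gene Magea4 (adjusted p = 1.1e-04). The Daxx effect on L1Md_T was smaller than in serum by a difference of -1.01 in 2i and -1.67 in retinoic acid, and that on MMERVK10C-int was larger by 1.43 in 2i. In all 7757 genes (5678 up and 2079 down) and 188 repeats (151 and 37) differed between 2i and serum, and 1475 genes (867 and 608) and 19 repeats (5 and 14) between retinoic acid and serum. Leaving out 1 library took the 1475 genes to 839 without Daxx-null retinoic acid replicate 2, 957 and 951 without wild-type retinoic acid replicates 1 and 2, 960 without Daxx-null serum replicate 1, and 967 and 903 without wild-type serum replicates 1 and 3. The 19 repeats became 11 without Daxx-null serum replicate 2 or wild-type retinoic acid replicate 1, and 12 without Daxx-null serum replicate 3 or wild-type serum replicates 1 or 3. With a replicate block these counts were 870 genes and 12 repeats, and without Daxx-null 2i replicate 2 the genes were 2344. The upward share between 2i and serum went from 73.2% to 46.7% of genes under quantile normalization (60.3% with median-ratio scaling). It went from 80.3% to 38.5% of repeats (58.8% with the genes' factor). Between retinoic acid and serum it went from 58.8% to 46.2% of genes (47% with median-ratio scaling).

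Genes lower in Daxx-null cells overlapped between serum and retinoic acid, 169 against 77.2 for independent lists (adjusted p = 2.5e-25), H19, Grb10, Nnat, Tuba3a and Srgn among them. The genes higher in both numbered 22 against 3.72 (one-sided Fisher test, adjusted p = 2.3e-12), and the fold changes had r = 0.282 across genes, which are not independent replicates. Chromosome 1 held 13.9% of the genes higher in serum and 42.5% of those higher in retinoic acid, against 5.75% of tested genes. Its shift may thus enter the overlap of higher genes, which was not counted with chromosome shifts removed. Between serum and 2i 611 genes were lower in both against 522 (adjusted p = 8.8e-06) and 518 higher against 527 (0.787), with r = -0.0329. Between 2i and retinoic acid the counts were 63 against 62.6 (0.663) and 16 against 12.6 (0.25), with r = -0.0743. These comparisons share no library. Without Daxx-null retinoic acid replicate 2 the overlap of 169 was 99 against 39.6 for independent lists, and without wild-type retinoic acid replicate 3 it was 100 against 41.9. With both 2i libraries that stand apart left out it was 426, but the retinoic acid list was then longer. The number for independent lists was not worked out there.

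Genes of chromosome 1, among them Hjurp, Nuf2, Slc40a1, Sp110 and Nmnat2, were higher as a body in Daxx-null cells. The median shift of 687 chromosome 1 genes against all genes was 0.295 in serum, 0.492 in 2i and 0.188 in retinoic acid. Without wild-type replicate 3 of the culture it was 0.226, 0.459 and 0.113. Chromosome 1 held 13.9%, 11.5% and 42.5% of the higher calls against 5.75% of tested genes. In 2i chromosome 14, which carries Klf5 and Gata4, was shifted by 0.485, chromosome 6 by -0.389 and chromosome 19, with Kif11 and Incenp, by -0.394. Wild-type 2i minus wild-type serum was shifted the opposite way, by -0.282 on chromosome 14, 0.446 on 6, 0.26 on 19 and -0.213 on 1. The 2i shifts therefore cannot be assigned to the Daxx-null cells alone. Chromosome 11, with Grin2c and Grb10, was shifted by -0.132 in serum, -0.0509 in 2i and -0.129 in retinoic acid. Without wild-type replicate 3 of the culture these values were -0.136, -0.0599 and -0.11. A fold change of a gene on any of these chromosomes includes the shift of its chromosome.

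**Figure D4:**
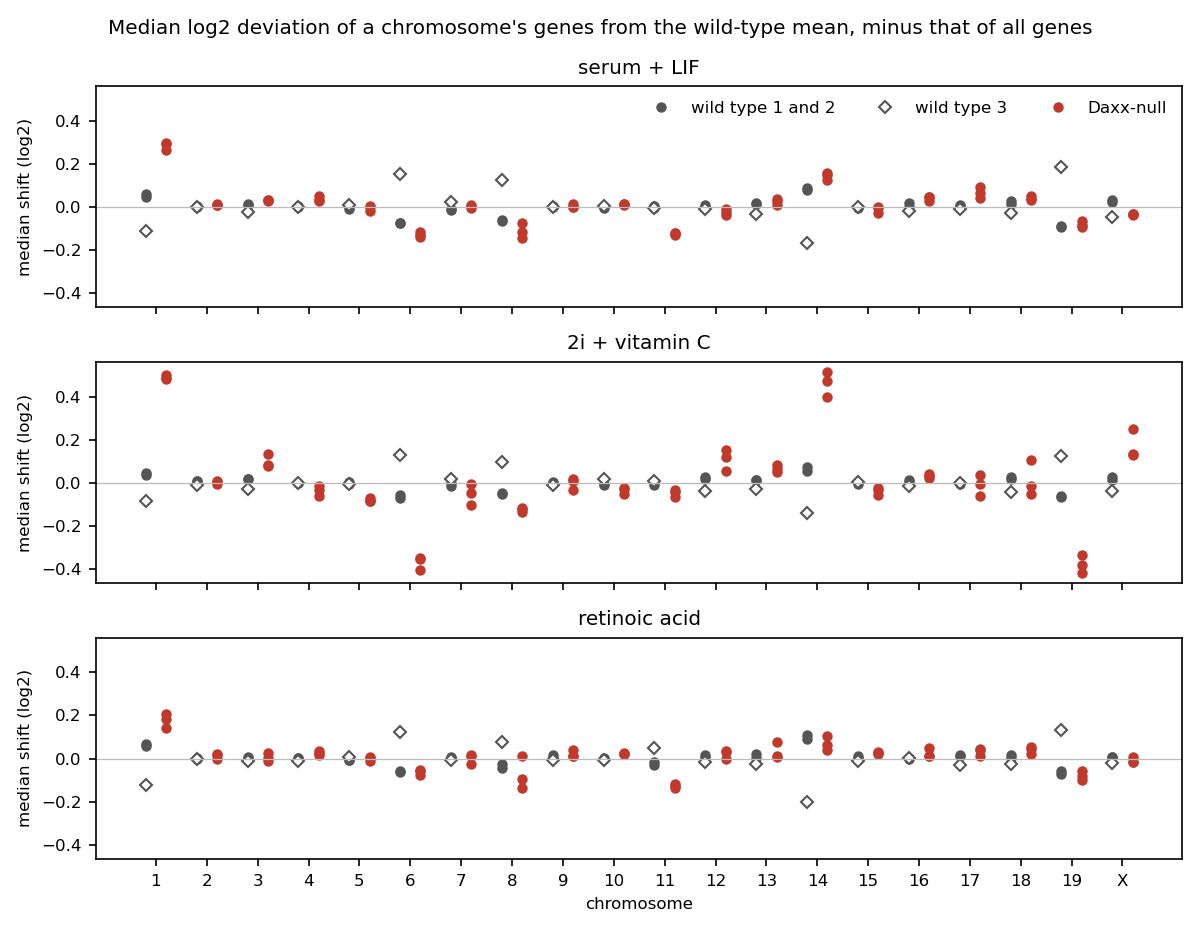
Median log2 deviation of the genes of each chromosome from the wild-type mean, minus that of all genes, for each library (points), by culture, with wild-type replicate 3 as open diamonds. Chromosome 1 lies at 0.295, 0.492 and 0.188 in Daxx-null minus wild-type cells of serum, 2i and retinoic acid, and wild-type replicate 3 stands apart on chromosomes 6, 14 and 19.

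Between wild-type cultures, retinoic acid lowered pluripotency genes. Nanog went from 2036 ± 149 to 4.19 ± 1.47 FPKM (log2 of retinoic acid minus serum -8.81), Tdgf1 from 3456 ± 346 to 1.27 (-10.98, adjusted p = 9.7e-14). In all, 28 of 28 pluripotency genes fell (28 adjusted over the list alone; adjusted p = 1.8e-18, 0.0683 with an estimated correlation). Retinoic acid response and Hox genes rose in 31 and fell in 2 of 33, with the nuclear receptor gene Nr2f1 going from 0.563 ± 0.264 to 1058 ± 180 (9.98; list adjusted p = 1.5e-14, 0.149 with an estimated correlation). Zic1 (6.81) was among 23 neural genes that rose while 3 fell (adjusted p = 0.00218, 0.66 with an estimated correlation). Endoderm genes rose in 22 and fell in 1, with Ttr at 5.61 (adjusted p = 4.2e-06, 0.311 with an estimated correlation). In all 5476 genes were higher and 6131 lower (3277 and 3193 at least 2-fold), with 432 and 71 repeats.

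In wild-type 2i against serum, primed epiblast genes fell in 13 and rose in 0 of 18 (14 falls adjusted over the list alone; adjusted p = 5.6e-06, 0.128 with an estimated correlation). Lefty1 went from 615 ± 34.3 to 30.1 ± 11.6 FPKM (-4.40, adjusted p = 4.6e-09) and Pou3f1 at -4.29. The DNA methyltransferase genes Dnmt3l (-1.63), Dnmt3a (-1.53) and Dnmt3b (-1.30) fell. Retinoic acid response and Hox genes rose in 19 and fell in 4 of 33 (adjusted p = 2.2e-06, 0.7 with an estimated correlation). Cdx1 went from 14.0 ± 2.96 to 990 ± 450 (6.02) and Rarb from 0.833 ± 0.366 to 45.2 ± 4.24 (5.13). In all 4452 genes were higher and 4461 lower (2008 and 2141 at least 2-fold), with 83 and 435 repeats.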

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

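The tests of Y-linked and X-linked genes, of a gain of chromosome 1, of the wild-type libraries numbered 3 and of Daxx-null 2i replicate 2 were chosen only after the result was seen. The test of GC content and the counts over other splits of the samples were chosen before.

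A test of the difference between Daxx effects in 2 cultures (limma's interaction term) singled out the following results. Between 2i and serum it called 7757 genes and 188 repeats, and between retinoic acid and serum 1475 genes and 19 repeats. The difference 2i minus serum, in log2, was 6.48 for H19, 6.31 for Cxcl10, 6.04 for Psmb8, 5.88 for Gbp2b and 5.84 for Fmr1nb. It was -4.90 for Apol6, -4.29 for Nkx6-3, -4.25 for Nkx1-2 and -4.17 for Cd37. Retinoic acid minus serum it was 3.41 for Copz2, 3.12 for Magea4, 2.99 for Crxos, 2.98 for Trim52 and 2.87 for Lrrc31. It was -4.44 for Grin2c, -3.84 for Slc23a1, -3.75 for Zscan4d, -3.67 for Lgals9 and -3.62 for Samd5.

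For repeats the difference 2i minus serum was 3.35 for tRNA-Glu-GAG, 2.21 for MLT1J1-int, 2.21 for Ricksha_c, 2.03 for MER99, 1.97 for L1M3f, 1.72 for RLTR3_Mm, 1.43 for MMERVK10C-int and 0.687 for IAPEz-int. It was -2.04 for RLTR45-int, -1.95 for MMETn-int, -1.72 for tRNA-Trp-TGG, -1.57 for ETnERV-int, -1.57 for RLTRETN_Mm, -1.54 for RLTR4_MM-int and -1.01 for L1Md_T. Retinoic acid minus serum it was 1.83 for Ricksha_c, 1.65 for ETnERV3-int, 1.59 for RLTR13B2, 1.33 for RLTR27 and 0.638 for Charlie22a. It was -1.88 for RLTR4_Mm, -1.82 for L1Md_Gf, -1.77 for RLTR4_MM-int, -1.74 for ORSL-2a, -1.67 for L1Md_T, -1.25 for L1Md_A and -0.769 for MMERVK10C-int.

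The same test on gene lists gave the following adjusted p between 2i and serum, with that of an estimated correlation in brackets: G2/M 7.0e-06 (0.0239), interferon 7.0e-06 (0.451), pluripotency 7.0e-06 (0.353), silencing partners 7.0e-06 (0.0684) and endoderm 1.0e-04 (0.451). Next came centromere 3.0e-04 (0.0572), primed epiblast 0.00382 (0.216), p53 targets 0.00661 (0.638), germline 0.0131 (0.671). The last were fibroblast 0.0159 (0.638, and 0.0766 with both 2i libraries that stand apart left out), DNA methylation 0.0207 (0.104, and 0.0574 with chromosome shifts removed), blood and endothelium 0.0242 (0.451) and trophoblast 0.027 (0.529). Between retinoic acid and serum they were two-cell-like state 6.8e-13 (0.228), pluripotency 7.2e-13 (0.228), glycolysis 1.8e-10 (0.228), cholesterol synthesis 7.3e-09 (0.255), then germline 3.3e-05 (0.515), G2/M 0.0107 (0.228) and silencing partners 0.0123 (0.331). For repeat lists they were ETn and MusD 5.9e-08 (0.0235), IAP 0.00149 (0.192) and MMERVK10C with RLTR10 0.00149 (0.192) between 2i and serum, and young L1 0.0253 (0.111, and 0.156 with a replicate block) between retinoic acid and serum.

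Eif2s3y, Uty and Ddx3y and X-linked genes such as Fmr1nb were near 0 in Daxx-null serum and retinoic acid libraries and present in Daxx-null 2i libraries. Wild-type cells under a Daxx-null 2i label are argued against by Daxx, which in these libraries reached at most 14.3% of the lowest wild-type 2i level. A single deleted stretch of the X chromosome from Fmr1nb to Xlr3c is argued against by the genes between them. Of these, 13 of 16 stood above 50% of wild type in Daxx-null serum. A shorter deletion was not tested: Pnma5, Xlr3a and Xlr3b lie close together, between 70279320 and 70448269, with Fmr1nb outside. Absence of the Y chromosome from the Daxx-null serum and retinoic acid cells cannot be told apart from its silencing. All 3 Y-linked genes were under 5% of the wild-type serum mean in every one of these libraries, which both would give. Another clone in 2i and an effect of Daxx itself stay open as untested.

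Chromosome 1 genes were higher as a body in Daxx-null cells of each culture, and several chromosomes were shifted together in the wild-type libraries numbered 3. GC content is argued against, since removing its trend kept 92% of the chromosome 1 shift in serum (0.296 before and 0.273 after). A gain of chromosome 1 in part of the Daxx-null cells stays a candidate that the test could not decide. At least 9 of its 10 stretches of 20 megabases were above the median of all genes in every culture. That shows a shift spread along the chromosome, as the whole-chromosome shift that prompted the test already implied. It cannot tell a gain in Daxx-null cells from a lower level in wild-type cells. Wild-type chromosome 1 genes stood at -0.213 in 2i and 0.111 in retinoic acid against serum. Part of the Daxx-null minus wild-type shift in 2i may thus lie in the wild-type cells. The Daxx-null minus wild-type shifts were 0.295, 0.492 and 0.188 (0.226, 0.459 and 0.113 without wild-type replicate 3) against 0.585 for an extra copy in every cell. A chromosome difference shared by the wild-type cultures numbered 3 is consistent with the correlation of their shifts across 20 chromosomes, at least 0.94 between cultures (Spearman at least 0.77, permutation p = 1e-05, the smallest that 100000 resamples can give). Chromosomes were not counted, and no biological explanation from the design was tested.

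Neural genes such as Dcx, Tubb3 and Sst were high in Daxx-null 2i replicate 2 and not in its sisters, 28 of 40 by at least 4-fold. RNA of retinoic acid cells mixed into the library is argued against, since 14 of these genes exceeded every retinoic acid library, whereas Cyp26b1 stood at 15.17 against 1048 and Nr2f2 at 21.05 against 608.2 FPKM in the highest of those. A swap with a retinoic acid library is argued against by its correlation with its sisters, higher by at least 0.0735 than with any retinoic acid library, and a lower depth by its 103.6 M units, between those of its sisters. Spontaneous neural differentiation in that culture may be the source, with Pou5f1 at 1918 against a sister mean of 4720 FPKM, and RNA of other neural cells stays open as untested.

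Calls were also counted after other splits of the samples. For Daxx-null against wild type and for the wild-type cultures, the 10 splits of 3 against 3 are too few for a share under 0.05, and the real split gave the most calls (1 of 10) each time. For genes the real counts and the highest other were 5078 and 1 in serum, 8431 and 10 in 2i and 448 and 3 in retinoic acid. They were 8913 and 1 for wild-type 2i against serum, and 11607 and 0 for wild-type retinoic acid against serum. For repeats they were 93 and 0, 201 and 3, and 7 and 1. Every other of these splits mixes both real groups on each side, which widens the spread within groups. Low counts in them follow from any large difference and do not exclude chance. For the difference between 2i and serum 1 of 100 splits, the real one, reached 7757 genes (highest other 6708) and 1 reached 188 repeats (highest other 156). Splits were drawn within each culture, so another split can keep or reverse the real grouping in 1 culture. It then still holds the Daxx effect of that culture. The highest other counts came near the real ones, so this share does not exclude chance. Between retinoic acid and serum 4 of 100 splits reached 1475 genes (highest other 4256) and 2 reached 19 repeats (highest other 112). Both shares are under 0.05, but some splits had several times the real count. Which splits these were was not recorded, and those that keep or reverse the real grouping in 1 culture can give such counts. These counts alone therefore do not set the real split apart.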

How the results depend on the processing

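Removal of chromosome shifts, leaving out Daxx-null 2i replicate 2 from fits of other groups, leaving out both 2i libraries that stand apart, leaving out the wild-type libraries numbered 3, the all-read scale and the list without RLTR40 to RLTR47 were tests chosen only after the result was seen. Over all alternatives 378 of the counts and list totals stayed within 1.5 times their value and 103 did not. With each library left out 2124 named gene and repeat results kept their side of the threshold, 249 lost and 3 gained a call. The cause was not tested except where fewer samples or subfamilies are named. Under quantile normalization lower genes were 2093 in serum and 229 in retinoic acid. Genes in 2i were then 3739 higher and 4224 lower, and the overlap of falls in serum and retinoic acid was 102, from shorter lists than in the main fit. Higher repeats were 56 in serum, 2i repeats 72 higher and 153 lower, retinoic acid repeats 0 and 3, and those that differed between retinoic acid and serum 36. In the authors' normalised table lower genes were 2146 in serum and 230 in retinoic acid, genes in 2i 3725 higher and 4215 lower, and the overlap 103. Chromosome-centred values gave 2599 higher genes in serum. With only the groups compared (fewer samples), genes in 2i were 2724 higher and 1205 lower, and lower genes in retinoic acid 268. Genes that differed between retinoic acid and serum were 3739, repeats in 2i 28 and 8 and higher repeats in retinoic acid 2. Repeats that differed between retinoic acid and serum were 60 and named genes in retinoic acid still called 23 of 40. A pseudocount 10 times larger gave 2 higher and 23 lower repeats in retinoic acid. The genes' median-ratio factor gave 29 lower repeats in serum, 94 higher in 2i and 119 that differed between 2i and serum. The all-read scale gave 29 lower repeats in serum, 269 higher in 2i and 0 higher in retinoic acid. Without simple and low-complexity repeats, serum repeats were 31 higher and 63 lower. With an estimated correlation 3 of 53 gene list calls and 3 of 10 repeat list calls held.

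Without Daxx-null 2i replicate 2 in comparisons of other groups, higher genes in retinoic acid were 85, genes that differed between retinoic acid and serum 2344, lower repeats in serum 98 and repeats in retinoic acid 2 higher and 14 lower. With both 2i libraries that stand apart left out, genes in retinoic acid were 225 higher and 872 lower, genes that differed between retinoic acid and serum 3703, and the overlap 426. Repeats were then 56 higher and 161 lower in serum, 100 higher in 2i, 11 higher and 71 lower in retinoic acid, and 50 that differed between retinoic acid and serum. The neural list in 2i reversed without Daxx-null 2i replicate 2 (adjusted p = 0.0371) and with both left out (2.1e-04), as did its difference between 2i and serum with both left out (0.00229). Without the wild-type libraries numbered 3, higher repeats were 19 in serum and 3 in retinoic acid, and repeats in 2i were 94 higher and 25 lower.

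With each library left out in turn, genes in serum ranged from 1079 to 1377 higher and 2348 to 2832 lower. They ranged in 2i from 4615 to 5879 and 2425 to 3028, and in retinoic acid from 16 to 39 and 224 to 362. Genes that differed from serum ranged from 6649 to 8394 in 2i and 839 to 1162 in retinoic acid. Repeats ranged from 18 to 27 higher and 29 to 40 lower in serum, 109 to 182 and 26 to 72 in 2i, and 0 to 1 and 2 to 8 in retinoic acid. Those that differed from serum ranged from 127 to 202 in 2i and 11 to 18 in retinoic acid. Wild-type 2i against serum ranged from 3739 to 4937 higher and 3737 to 4144 lower genes, and retinoic acid from 5024 to 5114 and 5593 to 5972. The overlap ranged from 99 to 150. Named genes still called ranged from 64 to 69 in serum, 69 to 78 in 2i and 26 to 34 in retinoic acid. List calls without Daxx-null 2i replicate 2 were 59 for genes and 12 for repeats.

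Between genotypes the replicate numbers did not pair the samples, with r from -0.162 to 0.154 and 2 of 9 above 0.1. With a replicate block, higher genes in retinoic acid were 19 and genes that differed between retinoic acid and serum 870. Repeats were then 17 higher and 33 lower in serum, 0 and 0 in retinoic acid, 113 that differed between 2i and serum and 12 between retinoic acid and serum. In wild-type cultures, paired in 2i and serum, the replicate block left 4433 higher and 4488 lower genes. Depth limits low genes, whose values rest on few counting units.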

Other observations

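The tests of these observations were all chosen only after the result was seen, except the wild-type list tests.

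An X-linked cluster of genes of germ cells and placenta followed the Y-linked genes. Fmr1nb stood at 317 FPKM in Daxx-null 2i, 1.28 in serum and 0.242 in retinoic acid, against 324, 109 and 46.2 in wild type. Pnma5 stood at 163, 2.84 and 0.306 against 375, 85.1 and 7.79, and Xlr3a at 77.0, 0.327 and 0.094 against 99.1, 46.9 and 25.0. Mageb16 was listed at 0 in Daxx-null retinoic acid and at 1.55 in serum, against 5.58 and 14.9 in wild type, and at 17.8 against 14.5 in 2i. Their neighbour Fmr1 was at 250 against 214 in serum, and of 16 genes between Fmr1nb and Xlr3c, 3 were under 5% of wild type. The division of reads within the Xlr family is uncertain.

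Other groups separated the wild-type cultures. Germline genes rose in 25 and fell in 8 of 42 in 2i against serum (adjusted p = 1.0e-04, 0.751 with an estimated correlation) and fell in 30 and rose in 3 in retinoic acid (3.3e-06, 0.365 with an estimated correlation). Glycolysis genes fell in 19 of 21 in 2i (8.5e-11, 0.386 with an estimated correlation) and in 20 in retinoic acid (1.4e-07, 0.246 with an estimated correlation). Imprinted genes rose in 30 and fell in 5 of 45 in retinoic acid (2.0e-05, 0.313 with an estimated correlation), H19 going from 217 ± 63.8 to 6810 ± 1227 FPKM, and fibroblast genes in 15 and 3 of 21 (0.0076, 0.571 with an estimated correlation). G2/M genes fell in 18 of 20 in retinoic acid (6.4e-05, 0.0651 with an estimated correlation), DNA methylation genes fell in 8 and rose in 3 of 13, with Dppa3 at -5.55 (0.0347, 0.149 with an estimated correlation), centromere genes fell in 11 and rose in 2 of 16 (0.0451, 0.246 with an estimated correlation) and primed epiblast genes fell in 11 and rose in 4 of 18, with Lefty2 at -7.32 and Otx2 at -6.96 (0.0039, 0.237 with an estimated correlation). Cholesterol synthesis genes rose in 11 and fell in 1 of 19 in 2i (0.0178, 0.865 with an estimated correlation). Not called in 2i were pluripotency genes (0.367), with Dppa2 at 1.73 and Utf1 at -2.13, neural genes (0.485), with Neurod1 at -5.37, endoderm (0.772), G2/M (0.0534) and two-cell-like genes (0.0534).

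The wild-type libraries numbered 3 carried shifts of whole chromosomes in each culture. In serum, 2i and retinoic acid they were 0.276, 0.188 and 0.197 on chromosome 19, which carries Kif11, Incenp, Fas and Acta2, 0.227, 0.193 and 0.182 on chromosome 6 with Dppa3 and Tuba3a, and 0.191, 0.144 and 0.113 on chromosome 8. They were -0.25, -0.206 and -0.302 on chromosome 14, with Klf5, Gata4 and Bmp4, and -0.166, -0.126 and -0.185 on chromosome 1. Daxx-null 2i minus wild type was 0.485 for chromosome 14, 0.492 for chromosome 1, -0.389 for chromosome 6, -0.394 for chromosome 19 and -0.133 for chromosome 8. Wild-type replicate 3 is part of the mean subtracted there and so enters with the opposite sign. Without it these values were 0.387, 0.459, -0.3, -0.347 and -0.0978. With all wild-type libraries, wild-type 2i minus serum was shifted the opposite way on these chromosomes, by -0.282, -0.213, 0.446, 0.26 and 0.216.

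Daxx-null 2i replicate 2 had 834 genes at least 4 times above its sisters, 408 of them above every retinoic acid library. Tubb3 stood at 1204 FPKM against a sister mean of 189, Sst at 684.3 against 18.3, Mab21l2 at 162.3 against 4.83 and Hoxb8 at 440.8 against 6.78, while Nanog was at 2594 against 3420. In wild-type 2i replicate 3, Cxcl10 was listed at 0 against 2.09 and 2.99 in its sisters, Krt18 stood at 9.80 against 47.9 and 62.8, Fas at 0.138 against 2.2 and 2.44, and the glucose transporter gene Slc2a3 at 5477 against 2281 and 2277.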
